A study of Mus musculus with 12 samples.

How the data were processed

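Gene expression was measured on Illumina mouse bead arrays in cultured mouse colon intestinal subepithelial myofibroblasts (ISEMFs), the contractile stromal cells that lie beneath the gut epithelium. The 12 arrays came from 6 cell lines: 3 wild type (WT5, WT7 and WT13) and 3 null for the miR-143/miR-145 microRNA cluster (KO4, KO10 and KO15). Each line was hybridised once untreated and once after 24 h with 1 ug/mL lipopolysaccharide (LPS), a bacterial cell wall component sensed through TLR4. Per the labels' protocols, cells grew in DMEM with serum, insulin, transferrin and EGF, total RNA was taken with a miRNeasy kit and DNase, and biotinylated cRNA was made with a MessageAmp kit. The labels do not say that the lines came from separate animals, so p-values measure the spread between these lines, part of which may be technical.

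The deposited intensity values are mean bead signals on a linear scale without normalisation, per the file headers, and no background had been subtracted from them, since the lowest signal on any array was 90.08. The deposited detection p-value of each probe, per the file headers, compares its signal with the negative controls of the array. A second deposited table holds the authors' processed intensity values of the same arrays. From the values, that table is linear, not centred and quantile normalised: column medians were 122.4 to 122.5 and the rank correlation with the unnormalised signals was 1 on all 12 arrays. BeadStudio is named in the submitters' processing notes, and its version and settings are not given in the sources used here. The number of columns left unused was 0. Probe names came from a platform annotation table: 34885 of the 45281 probes had 1 gene symbol, 18 had several and 10378 had none. Entrez identifiers of 11044 of the 11060 genes tested were found in a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. That assembly was used for chromosome names and gene order only, since the build behind the array annotation is not given in the sources used here. Probes for miR-143, miR-145 and their host transcript were not analysed here, so the knockout could not be checked from the targeted gene.

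Signals were normalised with neqc in limma 3.58.1 under R 4.3.3, which fits the background from the detection p-values, adds an offset of 16, normalises by quantiles and takes log2. Probes with a detection p under 0.05 on at least 3 of the 12 arrays were kept (21124 probes, 17886 of them with 1 gene symbol). Each gene was represented by the probe with the highest mean log2 intensity, which gave 11060 genes. The 3238 kept probes with no single gene symbol were tested apart. A probe that no array of a group detected has only a bound there: the fold is then given as at least N-fold, the mean of the brighter group against the mean of, per array, the higher of the lowest detected signal and the probe's own signal. The share of probes detected per array was 42.5% to 44.7%, and the number of arrays limits the precision.

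There were 6 comparisons, made with lmFit and eBayes (two-sided) and Benjamini-Hochberg adjustment at 0.05. One fit of 4 group means over all 12 arrays gave KO against WT without LPS, KO against WT with LPS, LPS against untreated in WT and in KO, and the difference between the last 2 changes. It treated the 12 arrays as independent and pooled their spread, so its p-values rest on all 4 groups and not only on those compared. A separate fit compared the 6 line means, each over the untreated and the LPS array of a line. All untreated arrays were on one slide and all LPS arrays on the other, so LPS and slide cannot be told apart. Genotypes were compared within a slide, and a slide effect that adds the same amount to both genotypes cancels in the difference of LPS changes. Within each slide the WT lines held positions A to C and the KO lines positions D to F, so position and genotype cannot be told apart either. An exact permutation test of 3 against 3 could not go below 0.1 for any single gene.

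The arrays of a line are paired. The labels give the same line with and without LPS, and the deviations of a line's 2 arrays from their group means correlated across genes at 0.137 to 0.52. Each of the 6 lines correlated best with itself. Fits with the line as a fixed or a random block were alternatives.

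The following were fixed before the data were examined: the comparisons, the tests, 30 gene lists, the rule for the genes named, and most alternatives. The rule named, per comparison, up to 10 genes with the largest change in each direction among those past the threshold whose groups did not overlap, up to 4 called genes of each list, Igfbp5 (reported as a target of this microRNA cluster) and members of the target list past the threshold adjusted over the list alone. Where fewer than 10 genes were called, the 10 of smallest p were named. The lists were miR-143/miR-145 reported targets, neighbours of the miR-143/miR-145 locus, IGF axis, smooth muscle contractile genes, fibroblast and myofibroblast genes, collagens and matrix, matrix proteases and inhibitors, NF-kB pathway feedback genes, chemokines, cytokines and colony stimulating factors, interferon-stimulated genes, antigen presentation, acute phase and complement, prostaglandin pathway, TLR4 signalling components, cell cycle, Wnt, BMP and hedgehog niche genes, EGF family and other epithelial growth factors, cholesterol synthesis, glycolysis and hypoxia, oxidative stress, endoplasmic reticulum stress, immediate early and heat shock, positional Hox, and sex-linked genes. Markers of epithelial cells, macrophages and leukocytes, endothelium, glia and neurons, and mesothelium with interstitial Cajal cells completed the 30. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry (one-way and either-way), adjusted over the 30 lists of a comparison.

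The fits were tested on simulated data in which 200 of 11060 genes had set fold changes. Without LPS, the genotype fit called 58.2% of genes set at 1.5-fold, 91% at 2-fold and 100% at 4-fold. With LPS these shares were 56.7%, 85.1% and 100%, and for line means 77.6%, 100% and 100%. The LPS comparison called 50.7%, 94% and 100% in WT and 64.2%, 91% and 100% in KO. For the difference of LPS changes the shares were 28.4%, 73.1% and 98.5%. False calls numbered 5 to 13 per comparison. The simulated noise was independent between arrays and between genes. The 2 real arrays of a line share part of their deviation, so the shares for line means may be too high for these data. The 200 set genes also outnumber the 20, 36 and 14 genes called in the real genotype comparisons and the 0 called for the difference. Fewer changed genes make the adjusted threshold stricter, so the shares for those comparisons may be too high as well.

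Alternatives covered the background correction (none, or normexp with an offset of 50), scaling to the 75th percentile, the authors' processed values, 3 other filters on dim probes, all probes or the mean of a gene's probes, a variance trend with robust eBayes, array weights, only the arrays compared, the line as a block, and leaving out each array in turn. Chosen after seeing the data were 4 more: sex of the line as a term, the leukocyte marker median as a covariate, and leaving out both arrays of line WT13 or of line KO4.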

Results

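The 12 arrays fell into 4 groups of 3: WT untreated, KO untreated, WT with LPS and KO with LPS, where KO stands for lines null for miR-143/miR-145. The design asks which transcripts differ in colon myofibroblasts that lack this microRNA cluster, how the cells respond to LPS, and whether the response depends on genotype. Median unnormalised signals were 115.5 to 136.1 per array, and 19223 to 20249 probes were detected. Of 20 contractile smooth muscle genes with probes, among them Acta2 and Myh11, 16 were detected on all 12 arrays, and of the fibroblast and myofibroblast genes 18 of 20. The same held for 11 of 20 macrophage and leukocyte markers and 4 of 12 glial and neuronal markers. It held for 5 of 20 epithelial, 4 of 15 endothelial and 3 of 11 mesothelial and Cajal cell markers. Among the genes tested, the median level of the kept members lay at percentile 94.4 for contractile and 59.9 for fibroblast genes. It lay at 64.6 for glial, 34.2 for leukocyte, 22.8 for endothelial, 19.9 for mesothelial and 17.9 for epithelial markers. The first principal component (56.9% of the variance) separated LPS from untreated arrays, and the second (11.1%) had all WT arrays at 0.4 to 25 and all KO arrays at -16 to -1.6, with the LPS array of WT13 farthest out at 25. That array correlated least with its group (mean r 0.9869, against 0.9901 to 0.995 for the others). Xist and Eif2s3y showed a male pattern in WT13 and KO10 and a female pattern in the other 4 lines, so each genotype had 1 male line. No 2 arrays held identical values, and the highest correlation between arrays was 0.9955.

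Without LPS, 13 genes were higher and 7 lower in lines lacking miR-143/miR-145, with Mdk and the pro-apoptotic gene Pmaip1 at the smallest p. Mdk, which encodes the growth factor midkine, was higher by 1.25 log2 units (SE 0.10, adjusted p = 0.000265), at 8.63 ± 0.08 (SD, n = 3) against 7.38 ± 0.12 (SD, n = 3) in WT. Pmaip1 was the gene with the largest fall, at 6.43 ± 0.17 (SD, n = 3) against 8.12 ± 0.29 (SD, n = 3), a log2 difference of -1.69 (SE 0.15, adjusted p = 0.0003). The fibrillar collagen gene Col24a1 was higher by 1.45 (SE 0.16, adjusted p = 0.00305). The Wnt ligand gene Wnt7b, not detected in untreated WT lines, was at least 1.66-fold higher (adjusted p = 0.00375). Fgf10, a mesenchymal growth factor for epithelium, was higher by 0.76 (SE 0.12, adjusted p = 0.0307).

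The other named genes that were higher without LPS were Tmem176b (1.40), Rerg (1.40), Cdh4 (1.28), Lgi2 (1.09), Clcn3 (0.85) and the DNA polymerase gene Poli (0.80). The other lower genes were the amine oxidase gene Aoc3 (-1.53), Stard6 (-0.99), Emcn (-0.80), Fjx1 (-0.73), the homeobox gene Gbx2 (-0.72) and Neto1 (-0.70). Pmaip1, Stard6, Poli and Neto1 lie on chromosome 18 of GRCm38.p6, the chromosome of the microRNA cluster. In all, 20 of 11060 genes differed (13 higher and 7 lower, 9 of them at least 2-fold), and 1008 had an unadjusted p under 0.05. The 2 groups did not overlap for 18.7% of genes, where chance gives 10%. With the authors' processed values 13 genes were higher and 2 lower, and with only the arrays compared 2 were higher and 1 lower. With 1 array left out, 9 (WT5), 6 (WT7), 6 (WT13), 11 (KO4), 5 (KO10) and 46 (KO15) genes were called, and Mdk, Pmaip1, Rtkn, Col24a1 and Wnt7b were the 5 named genes called in each of these 6 fits.

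Reported targets of miR-143/miR-145 had a median difference of 0.12 without LPS, higher as a group by camera (adjusted p = 0.00557) but not with an estimated correlation (adjusted p = 0.153), and higher by fry (adjusted p = 0.000604). Of 31 measured, 20 had a positive difference and 2 passed the test over all genes. These were Rtkn at 0.93 (SE 0.10, adjusted p = 0.00287), and Tgfbr2, a TGF-beta receptor gene, at 0.57 (SE 0.09, adjusted p = 0.0294). Adjusted over the list alone, 4 were higher, the others being Pdgfra (0.76, SE 0.17) and Fscn1 (0.56, SE 0.14), whose p adjusted over all genes was 0.125 and 0.171. Igfbp5, a binding protein gene of the IGF axis, stood at 9.3 ± 1.16 (SD, n = 3) in KO against 7.99 ± 0.22 (SD, n = 3) in WT and did not pass (1.31, SE 0.52, adjusted p = 0.436). Its KO lines spread widely: KO10 and KO15 were at 9.96 and 9.97, while KO4 was at 7.96, within the range of the WT lines (7.74 to 8.17). Without both arrays of line KO4, a setting chosen after seeing the data, the difference was 1.98 (adjusted p = 0.000329, with a range of 0.000329 to 0.87 over all alternatives). Since KO4 was the KO line at the WT level, leaving it out favours a difference, and this value lends no support.

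Interferon-stimulated genes also lay higher in untreated KO lines, 23 of 25 with a positive difference and a median of 0.33 (camera adjusted p = 5.11e-05, and adjusted p = 0.508 with an estimated correlation). No member passed on its own, with Usp18 at 1.44 (SE 0.39, adjusted p = 0.201) and Isg15 at 1.13 (SE 0.35, adjusted p = 0.284). The per-array medians of the list overlapped, at 6.36, 6.09 and 5.71 in WT5, WT7 and WT13 and 6.28, 6.72 and 6.06 in KO4, KO10 and KO15, and the median difference ranged from 0.15 to 0.50 over alternatives. All 15 cholesterol synthesis genes were positive, with a median of 0.18 (adjusted p = 0.00147, and 0.331 as the adjusted p with an estimated correlation). Wnt, BMP and hedgehog niche genes had 12 of 16 members positive and a median of 0.18, and 4 passed adjusted over the list alone, among them Bmp4 at 1.18 (SE 0.24, adjusted p over all genes 0.0846). Their camera adjusted p was 0.00743 (adjusted p = 0.331 with an estimated correlation, and adjusted p = 0.0569 without the WT13 array, the highest of a range from 0.00424). Glycolysis and hypoxia genes had a median of 0.16 (adjusted p = 0.00557, adjusted p = 0.507 with an estimated correlation, and adjusted p = 0.128 without the KO10 array, the highest of a range from 0.000346). Acute phase and complement genes had a median of 0.15 (adjusted p = 0.0296, and adjusted p = 0.508 with an estimated correlation), and mesothelial and Cajal cell markers one of 0.40 with 7 of 7 positive (adjusted p = 0.0466, and adjusted p = 0.507 with an estimated correlation). Of 10 other camera settings 4 kept the acute phase call and 4 the mesothelial call, and without the untreated WT13 array the mesothelial median was -0.046 (adjusted p = 0.358).

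Smooth muscle contractile genes and glial markers had negative medians without LPS. Of 19 contractile genes 3 were positive, with a median of -0.14 (camera adjusted p = 0.00241, and adjusted p = 0.507 with an estimated correlation). Adjusted over the list alone 2 were lower, Smtn (-0.36, SE 0.09) and Csrp1 (-0.34, SE 0.10). The 5 glial and neuronal markers had a median of -0.33 (adjusted p = 0.0417, and adjusted p = 0.331 with an estimated correlation, called in 5 of 10 other camera settings), led by Sox10 at -0.95 (SE 0.32, adjusted p over all genes 0.318). Macrophage and leukocyte markers, which stood beside these groups, had a median of -0.31 with 4 of 18 positive and did not pass (adjusted p = 0.0947). The 16 neighbours of the microRNA locus had 0 members called and a median of -0.12 (adjusted p = 0.0968), although they were among the 8 lists that passed the test for change in either direction (fry adjusted p = 0.00374). Epithelial growth factors (8.26e-08), collagens and matrix (4.78e-05), fibroblast genes (0.0357) and endothelial markers (0.0438) passed that test without passing camera. Collagen and matrix genes had a median of -0.06 but a mean of 0.08 (adjusted p = 0.768), and epithelial growth factor genes a median of 0.05 with Fgf10 the 1 called of 19 (adjusted p = 0.876). The 5 sex-linked genes on the list had 4 measured members (median 0.07, adjusted p = 0.985), the Hox genes a median of 0.03 and a mean of -0.01 (adjusted p = 0.985), epithelial markers a median of -0.03 (adjusted p = 0.543) and endothelial markers one of 0.06 beside a mean of -0.07 (adjusted p = 0.838).

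**Figure D1:**
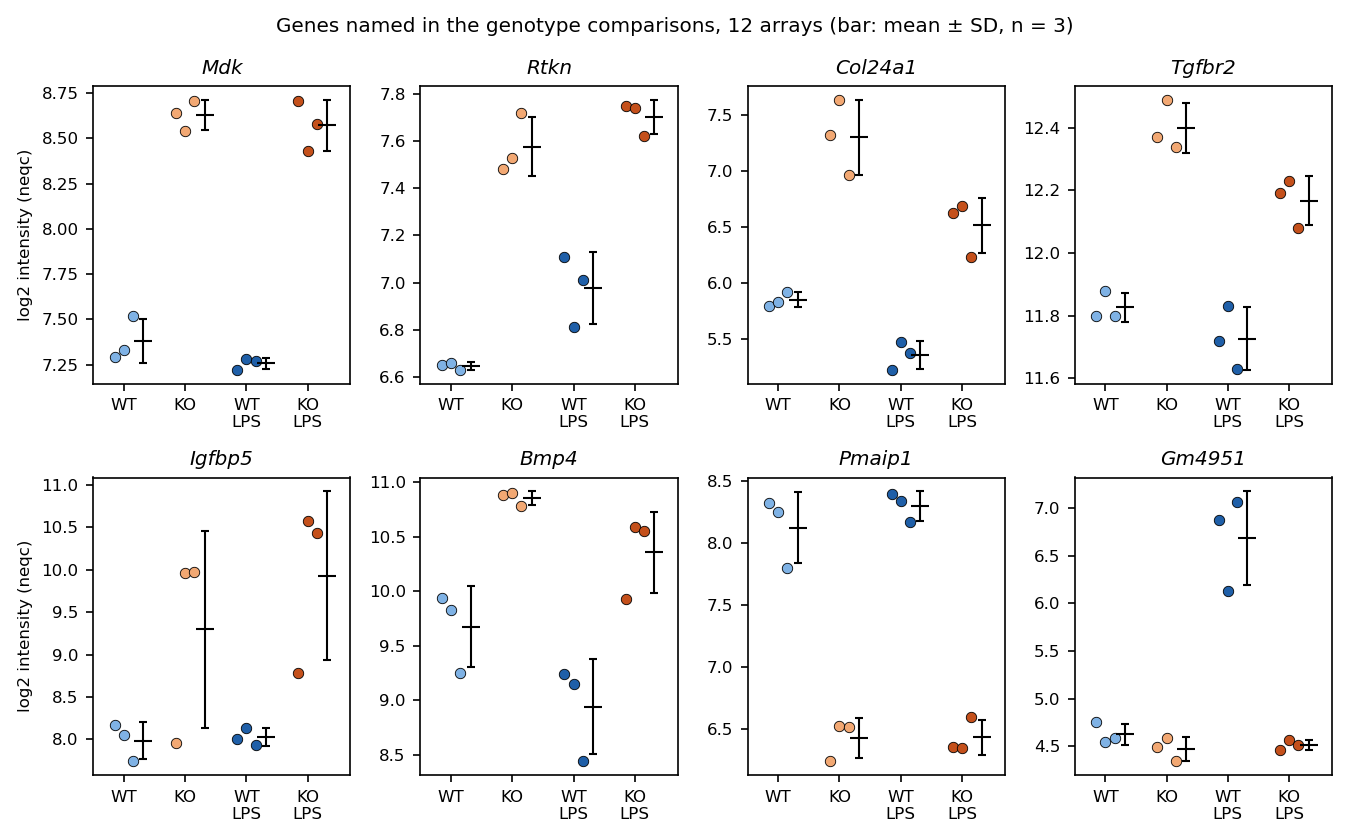
Normalised log2 intensity of 8 genes on each of the 12 arrays by group, with the mean ± SD of 3 arrays beside the points. Mdk lay above every WT array on each KO array in both conditions, Igfbp5 was within the WT range in untreated KO4, and Gm4951 was detected on the 3 WT arrays with LPS.

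After LPS, 25 genes were higher and 11 lower in KO than in WT lines. Tgfbi, a secreted matrix protein gene induced by TGF-beta, was higher by 1.83 (SE 0.34, adjusted p = 0.0459), and the laminin gene Lama1 by 1.57 (SE 0.27, adjusted p = 0.038). Bmp4, which encodes a morphogen of the crypt niche, stood at 10.36 ± 0.37 (SD, n = 3) against 8.94 ± 0.44 (SD, n = 3), a difference of 1.41 (adjusted p = 0.0361). Hgf, the hepatocyte growth factor gene, was higher by 0.97 (SE 0.15, adjusted p = 0.0254), and the complement inhibitor gene Serping1 by 1.44 (SE 0.24, adjusted p = 0.0305). The interferon-inducible GTPase gene Gm4951 was at least 3.41-fold lower (adjusted p = 0.000213), since no KO array with LPS detected it.

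Mdk (1.31, SE 0.10, adjusted p = 9.77e-05) and Pmaip1 (-1.87, SE 0.15, adjusted p = 9.77e-05) again differed. The eosinophil chemokine gene Ccl11 (1.31), Tmem176b (1.20), Lgi2 (1.20), Col24a1 (1.17), Fam13c (1.10) and Fgf10 (0.68) were higher too. Nme7 (-1.16), the sodium pump subunit gene Atp1b1 (-1.04), Stard6 (-0.93), Gbx2 (-0.91), Igsf11 (-0.80), Ggct (-0.76), Emcn (-0.74) and the kinase gene Tnik (-0.65) were lower. The count was 36 genes (25 higher and 11 lower, 15 at least 2-fold), with 1198 at an unadjusted p under 0.05 and 13.2% of genes without overlap between the groups, where chance gives 10%. It was 9 (WT5), 14 (WT7), 15 (WT13), 27 (KO4), 6 (KO10) or 17 (KO15) with 1 array left out, and Mdk, Pmaip1, Gm4951, Gbx2 and Nme7 were the named genes called in each of those 6 fits. Higher and lower genes numbered 3 and 6, 9 and 5, 7 and 8, 17 and 10, 1 and 5, and 9 and 8 in the same order. With only the arrays compared, 3 genes were higher and 4 lower.

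All 15 cholesterol synthesis genes were positive between genotypes with LPS, with a median of 0.25 (camera adjusted p = 3.6e-07, adjusted p = 0.122 with an estimated correlation, fry adjusted p = 0.0071). Stard4, a sterol transfer protein gene on chromosome 18, passed over all genes at 0.90 (SE 0.15, adjusted p = 0.0302), and 3 passed adjusted over the list alone, with Sc5d at 0.60 and Insig1 at 0.58. IGF axis genes had 15 of 17 members positive and a median of 0.17 (adjusted p = 0.00265, adjusted p = 0.122 with an estimated correlation, fry adjusted p = 0.00385). The largest were Igfbp5 at 1.90 (SE 0.52, adjusted p = 0.201) and Igfbp4 at 1.18 (SE 0.25, adjusted p = 0.0909), and both passed adjusted over the list alone. Niche genes had a median of 0.14, with 1 member called and 5 adjusted over the list alone (adjusted p = 0.00654, adjusted p = 0.2 with an estimated correlation, fry adjusted p = 0.0316), among them Gli2 at 0.76 and Wnt5a at 0.50. Acute phase and complement genes had a median of 0.33 (adjusted p = 0.00265, adjusted p = 0.347 with an estimated correlation, and adjusted p = 0.0723 without the KO10 array, the highest of a range from 3.56e-05). Reported miR-143/miR-145 targets had a median of 0.089, with Rtkn called at 0.72 (SE 0.10, adjusted p = 0.014) and 4 adjusted over the list alone (group adjusted p = 0.044, fry adjusted p = 0.00257, and adjusted p = 0.2 with an estimated correlation, called in 4 of 10 other camera settings).

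Contractile genes were lower with LPS as well, 5 of 19 being positive, with a median of -0.15 (adjusted p = 0.000768, and adjusted p = 0.347 with an estimated correlation). Myl9 stood at -0.41 (SE 0.09, adjusted p = 0.0778) and Myh11 at -0.68 (SE 0.19, adjusted p = 0.213). Leukocyte markers moved with them, 1 of 18 positive and a median of -0.32 (adjusted p = 0.044, adjusted p = 0.81 with an estimated correlation, and adjusted p = 0.952 without the KO4 array, the highest of a range from 1.68e-07). The leukocyte marker median of KO4 with LPS was 5.57, against 6.25 to 6.74 on the other 5 LPS arrays. Over 10 other camera settings the list's median difference ranged from -0.72 to 0.12, and 4 kept the call. Glial markers had 0 of 5 members positive and a median of -0.23 (adjusted p = 0.044, and adjusted p = 0.2 with an estimated correlation, called in 3 of 10 other camera settings). Interferon-stimulated genes had a median of -0.15 with LPS and did not pass (adjusted p = 0.0775), nor did chemokines at -0.07 (adjusted p = 0.656) collagens and matrix genes at 0.13 (adjusted p = 0.0868, although fry passed at an adjusted p = 0.0145) or epithelial growth factor genes at -0.13 (adjusted p = 0.428). Fibroblast and myofibroblast genes had a median of -0.05 beside a mean of 0.11 and did not pass (adjusted p = 0.605).

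Genes called between genotypes with and without LPS went the same way where shared. Some lists had medians of opposite sign, such as interferon-stimulated genes. That list did not pass with LPS, and its call without LPS was lost with an estimated correlation. The 2 sets of called genes shared 12 genes with the same direction (8 higher and 4 lower) and 0 with opposite directions, where independent lists of these sizes would share 0.0294 and 0.00696. Differences correlated at r = 0.48 across genes, which are not independent replicates, and both sets come from the same 6 lines, so line differences enter both. On the 6 line means, 14 genes differed (7 higher and 7 lower), with 1138 at an unadjusted p under 0.05. Mdk (1.28, SE 0.08, adjusted p = 0.00195) and Pmaip1 (-1.78, SE 0.12, adjusted p = 0.00195) were the 2 genes called in all 19 alternatives. The others were Col24a1 (1.31), Tmem176b (1.30), Cdh4 (1.02), Rtkn (0.83), Clcn3 (0.77), Poli (0.76), Tnik (-0.55), Igsf11 (-0.66), Gbx2 (-0.82), Nme7 (-0.91), Stard6 (-0.96) and Gm4951, which was lower and which 9 of the 12 arrays did not detect. Groups without overlap made up 16.1% of genes, where chance gives 10%. With scaling to the 75th percentile 18 genes were higher and 9 lower, and with the authors' processed values 2 were higher and 1 lower. With 1 line left out, 3 (WT5), 3 (WT7), 4 (WT13), 49 (KO4), 7 (KO10) and 38 (KO15) genes were called.

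On line means 10 lists passed. Cholesterol synthesis (median 0.22, adjusted p = 7.23e-07), acute phase and complement (0.18, adjusted p = 0.00118), niche genes (0.13, adjusted p = 0.00228), reported targets (0.030 with 17 of 31 positive, adjusted p = 0.0128), glycolysis and hypoxia (0.12, adjusted p = 0.0153), the IGF axis (0.13, adjusted p = 0.0196) and mesothelial and Cajal cell markers (0.24, adjusted p = 0.0251) were higher. Their adjusted p with an estimated correlation was 0.307, 0.475, 0.307, 0.307, 0.787, 0.307 and 0.488. Contractile genes (-0.21, adjusted p = 8.05e-05), glial markers (-0.28, adjusted p = 0.00828) and leukocyte markers (-0.29, adjusted p = 0.0196) were lower, with an adjusted p = 0.475, 0.307 and 0.87 with an estimated correlation. Adjusted over the list alone, 7 contractile genes were lower and 6 reported targets higher, including Cdk6 (0.27, SE 0.07) and Igfbp5 (1.61, SE 0.45, adjusted p over all genes 0.256). The glycolysis call was lost without line KO10 (adjusted p = 0.239, range 0.000207 to 0.239 over 10 settings) and the IGF call without WT13 (adjusted p = 0.0529, range 0.00667 to 0.0529). The leukocyte and the mesothelial call were each kept in 5 of 10 settings, with ranges of 2.87e-13 to 0.705 and 0.000146 to 0.249.

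Inflammatory transcripts rose broadly in the WT lines with LPS. LPS and slide coincide, and which cells in the cultures made these transcripts was not tested. Lcn2, the antimicrobial lipocalin gene, rose by 5.97 (SE 0.60, adjusted p = 7.43e-05), from 4.84 ± 0.52 (SD, n = 3) to 10.8 ± 0.14 (SD, n = 3). Saa3, an acute phase gene, rose by 5.74 (SE 0.67), and the neutrophil chemokine gene Cxcl1 by 5.16 (SE 0.58). Il1b, which encodes a pro-inflammatory cytokine, rose at least 39.5-fold and Cxcl2 at least 26.5-fold, since no untreated WT array detected either. In the other direction, the collagen-binding integrin gene Itga11 fell by 2.05 (SE 0.31, adjusted p = 0.000986) and the growth factor gene Tgfb3 by 1.95 (SE 0.17, adjusted p = 4.04e-05). Aoc3 (-2.01), the growth factor gene Ptn (-1.85), the matrix Gla protein gene Mgp (-1.77) and Ogn (-1.69) fell too.

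Immune gene groups accounted for the largest rises in WT. Of 25 interferon-stimulated genes 22 rose, with a median of 2.23 (camera adjusted p = 7.36e-22, and adjusted p = 0.101 with an estimated correlation), for example Usp18 (4.38), Oasl2 (4.31), Trim30a (4.17) and Isg15 (4.12). Of 17 chemokines 15 rose, with a median of 2.71 (adjusted p = 2.1e-15, and adjusted p = 0.101 with an estimated correlation), including Ccl2 (5.20), Ccl3 (4.72) and Ccl5 (4.68). NF-kB feedback genes rose in 13 of 16 cases, with Nfkbia at 1.95 and Tnfaip3 at 1.71 (median 1.04, adjusted p = 2.14e-13, and adjusted p = 0.101 with an estimated correlation). Of 16 antigen presentation genes 12 rose, with H2-K1 at 2.32 and Psmb8 at 1.96 (median 0.74, adjusted p = 1.31e-09, and adjusted p = 0.164 with an estimated correlation). Of 19 cytokines and colony stimulating factors 8 rose, Il1a by 4.24 and Il6 by 2.82 among them, and Csf2 at least 8.22-fold (median 0.65, adjusted p = 6.81e-09, and adjusted p = 0.101 with an estimated correlation). Acute phase and complement genes rose in 5 of 13 cases, Ptx3 at least 10.6-fold (median 0.40, adjusted p = 7.75e-05, and adjusted p = 0.198 with an estimated correlation). Of 8 prostaglandin pathway genes 3 rose: Ptges by 2.07, Ptgs2 by 1.68 and Ptges3 by 0.97 (median 0.25, adjusted p = 0.0111, and adjusted p = 0.101 with an estimated correlation).

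Metabolic and structural groups also changed in WT. Of 20 glycolysis and hypoxia genes 8 rose, led by Egln3 (1.41) and Adm (1.37) (median 0.22, adjusted p = 1.61e-05, and adjusted p = 0.198 with an estimated correlation), and of 19 oxidative stress genes 8 rose and 1 fell, with the heme oxygenase gene Hmox1 at 1.45 (median 0.42, adjusted p = 0.000178, and adjusted p = 0.236 with an estimated correlation). Contractile genes fell in 13 of 19 cases: Myh11 by 1.28, Mylk by 1.15, Lmod1 by 1.14 and Tagln by 0.61 (median -0.42, adjusted p = 2.19e-05, and adjusted p = 0.198 with an estimated correlation). Acta2 lay at the top of the scale on all 12 arrays (15.19 to 15.28), where a change would hardly show. Of 18 collagen and matrix genes 8 fell, with Tgfbi at -1.59 and Fn1 at -0.75 (median -0.35, adjusted p = 0.000329, and adjusted p = 0.0917 with an estimated correlation), and Loxl1 (-0.46) has another probe called in the opposite direction. The IGF axis did not pass camera with 0 genes up and 5 down of 17 (median -0.21, adjusted p = 0.144), while fry did (adjusted p = 0.00035), and cholesterol synthesis had 0 up and 3 down of 15 (adjusted p = 0.66). Several others that did not pass camera held called members going both ways. Among matrix proteases and inhibitors 6 rose, including Mmp3 (3.65), Mmp13 (3.33) and Mmp9 (2.76), and 5 fell (list adjusted p = 0.55), and of 18 endoplasmic reticulum stress genes 7 rose and 4 fell (adjusted p = 0.263, fry adjusted p = 0.0209). Of 19 epithelial growth factor genes 5 rose, with Fgf7 at 1.62, and 2 fell (adjusted p = 0.265). Of 19 TLR4 signalling components 5 rose, with Tlr2 at 1.41 and Cd14 at 1.62, and 3 fell (adjusted p = 0.364). Of 28 cell cycle genes 4 rose, with Pcna at 1.07, and 1 fell (adjusted p = 0.66). Of 17 immediate early and heat shock genes 1 rose and 4 fell, with Egr2 at -1.20 and Klf2 at -0.94 (adjusted p = 0.7, fry adjusted p = 0.0376). Leukocyte markers had 3 genes up, with Adgre1 at 2.12, and 2 down, with C1qc at -1.70 (median -0.20, adjusted p = 0.987). Reported microRNA targets went both ways with LPS in WT (4 up and 6 down of 31, median -0.08 beside a mean of 0.015, adjusted p = 0.987, fry lower at an adjusted p = 0.0328), as did fibroblast and myofibroblast genes (3 up and 3 down of 20, median -0.09 beside a mean of 0.023, adjusted p = 0.949). Niche genes had 1 up and 6 down of 16 (adjusted p = 0.26, fry adjusted p = 0.0153).

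In all, LPS changed 2526 of 11060 genes in WT (1162 higher and 1364 lower, 377 at least 2-fold, and 1059 higher and 1686 lower with scaling to the 75th percentile), with 4142 at an unadjusted p under 0.05 and 39.9% of genes without overlap, where chance gives 10%. The count was 1666 and 1581 without the untreated array of WT7 or WT13, and 1097 without both arrays of WT13, the line whose LPS array stood apart. All 11 list calls were kept with each array left out.

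Largely the same genes changed with LPS in the KO lines. Lcn2 rose by 5.82 (SE 0.60, adjusted p = 0.000131), from 5.95 ± 1.43 (SD, n = 3) to 11.78 ± 0.95 (SD, n = 3), Saa3 by 5.35 (SE 0.67) and Cxcl1 by 4.85 (SE 0.58). Il1b rose at least 28.5-fold and Cxcl2 at least 25.9-fold. The metalloprotease genes Mmp3 (3.69), Mmp13 (3.58) and Mmp9 (3.18) rose, and the mesenchymal transcription factor gene Twist2 rose by 1.74 (SE 0.27, adjusted p = 0.00142). Itga11 fell by 1.98 (SE 0.31), the small proteoglycan gene Ogn by 1.93 (SE 0.20) and Tgfb3 by 1.81 (SE 0.17). Sprr2k (-1.93), Ccdc3 (-1.86), the guanylate cyclase subunit gene Gucy1a1 (-1.86) and Nrep (-1.77) fell as well.

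The groups that passed in KO were the 11 that passed in WT. Interferon-stimulated genes rose in 20 of 25 cases (median 1.66, camera adjusted p = 2.05e-19, and adjusted p = 0.102 with an estimated correlation), with Trim30a at 3.15, Oasl2 at 3.13 and Isg15 at 2.94. Chemokines rose in 15 of 17 cases (median 2.42, adjusted p = 7.41e-17, and adjusted p = 0.102 with an estimated correlation), NF-kB feedback genes in 13 of 16 (median 1.05, adjusted p = 8.51e-15, and adjusted p = 0.0835 with an estimated correlation) and antigen presentation genes in 11 of 16 (median 0.77, adjusted p = 1.23e-08, and adjusted p = 0.158 with an estimated correlation). Cytokines rose in 9 of 19 cases, with Il6 at 2.88 (median 0.60, adjusted p = 2.8e-08, and adjusted p = 0.102 with an estimated correlation), and acute phase genes in 7 of 13 (median 0.67, adjusted p = 3.05e-07, and adjusted p = 0.102 with an estimated correlation). Of 20 glycolysis genes 8 rose and 1 fell (median 0.33, adjusted p = 3.81e-06, and adjusted p = 0.168 with an estimated correlation), of 19 oxidative stress genes 7 rose and 1 fell (median 0.44, adjusted p = 1.88e-05, and adjusted p = 0.179 with an estimated correlation), and of 8 prostaglandin genes 4 rose (median 0.34, adjusted p = 0.00248, and adjusted p = 0.0935 with an estimated correlation). Contractile genes fell in 9 of 19 cases, with Myh11 at -1.50 and Lmod1 at -1.32 (median -0.41, adjusted p = 4.76e-07, and adjusted p = 0.138 with an estimated correlation). Collagen and matrix genes fell in 6 of 18 cases, with Tgfbi at -1.40 and Col5a1 at -0.52 (median -0.28, adjusted p = 0.00154, and adjusted p = 0.0835 with an estimated correlation). Matrix proteases and inhibitors did not pass (4 up and 6 down of 18, median -0.11 beside a mean of 0.60, adjusted p = 0.716), and reported targets passed fry as lower (adjusted p = 0.00725) but not camera (adjusted p = 0.716).

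LPS changed 1622 genes in KO (824 higher and 798 lower, 301 at least 2-fold), with 3144 at an unadjusted p under 0.05 and 37.1% of genes without overlap, where chance gives 10%. With scaling to the 75th percentile the split was 727 higher and 1062 lower. The count was 923 without the untreated array of KO4, 1014 without that of KO10, and 808 and 1027 without the LPS array of KO10 or KO15.

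**Figure D2:**
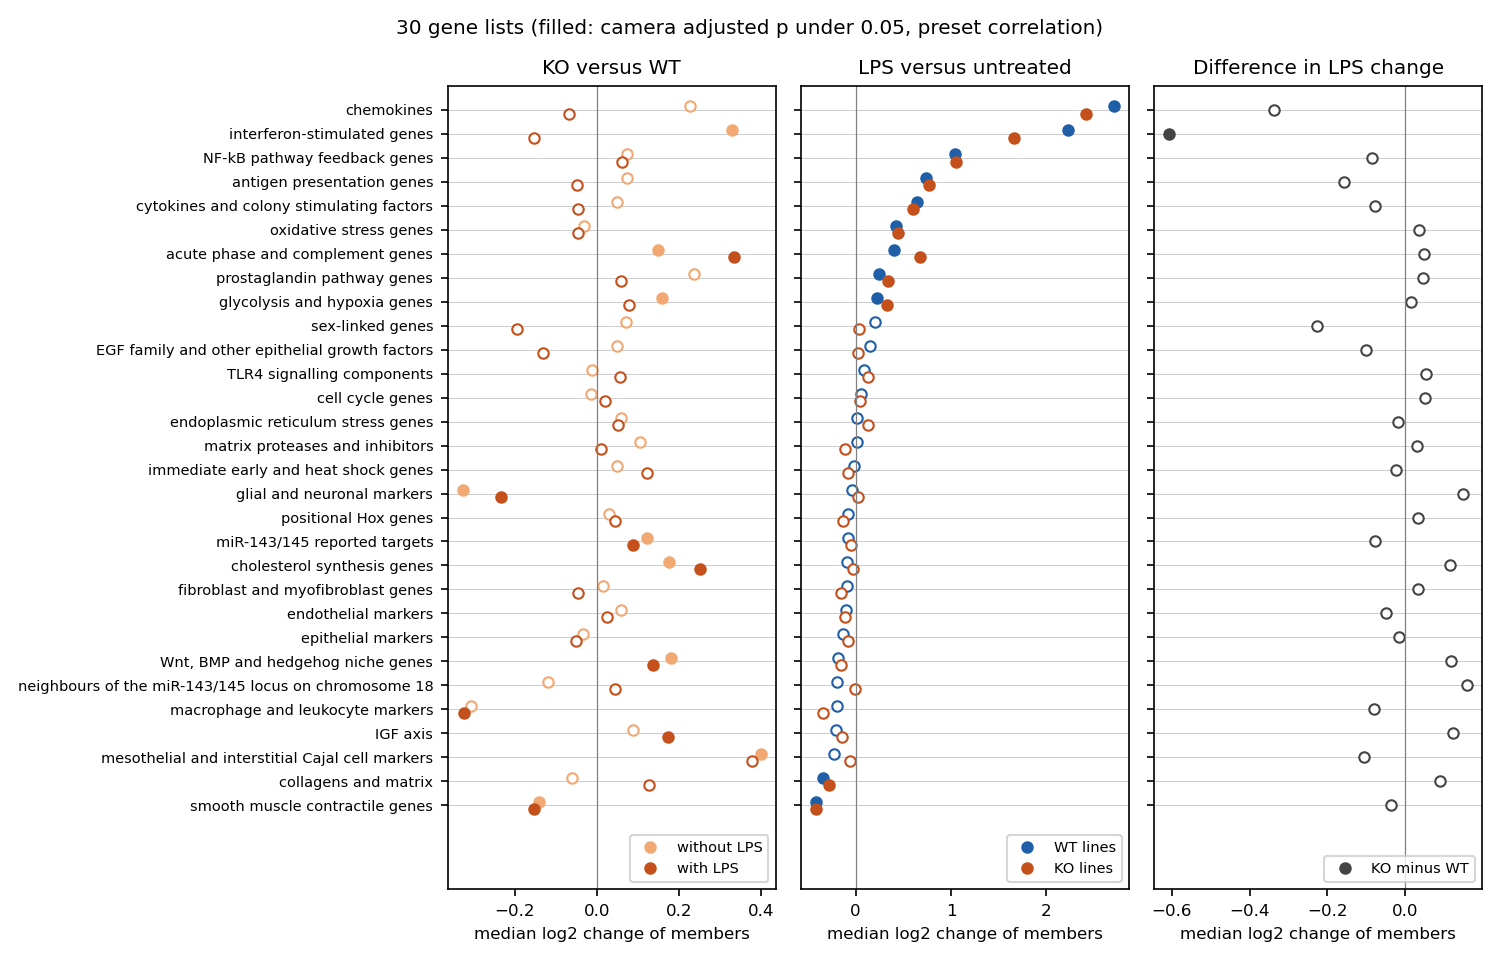
Median log2 change of the measured members of each of the 30 gene lists, for KO against WT, LPS against untreated, and the difference in LPS change (KO minus WT). Filled points passed camera with the preset correlation, and no list passed with an estimated correlation. Between genotypes, interferon-stimulated genes had a median of 0.33 without LPS and of -0.15 with LPS, where they did not pass. Their median difference in LPS change was -0.61.

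Responses of the 2 genotypes to LPS shared 1247 called genes with the same direction (649 higher and 598 lower) and 0 with opposite directions, where independent lists would share 86.6 and 98.4. Of the genes called in WT, 98.7% had the same sign in KO. Changes correlated at r = 0.888 across genes, which are not independent replicates. All LPS arrays lay on one slide and all untreated arrays on the other. A slide effect would therefore enter both changes and add to the sharing and to r, so independent lists are no full yardstick here. Of the 74 genes named in both comparisons, 74 had the same sign, and 52 had a larger absolute change in WT. The match in sign adds no support, since all 74 were called in both and no gene called in both went opposite ways.

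**Figure D3:**
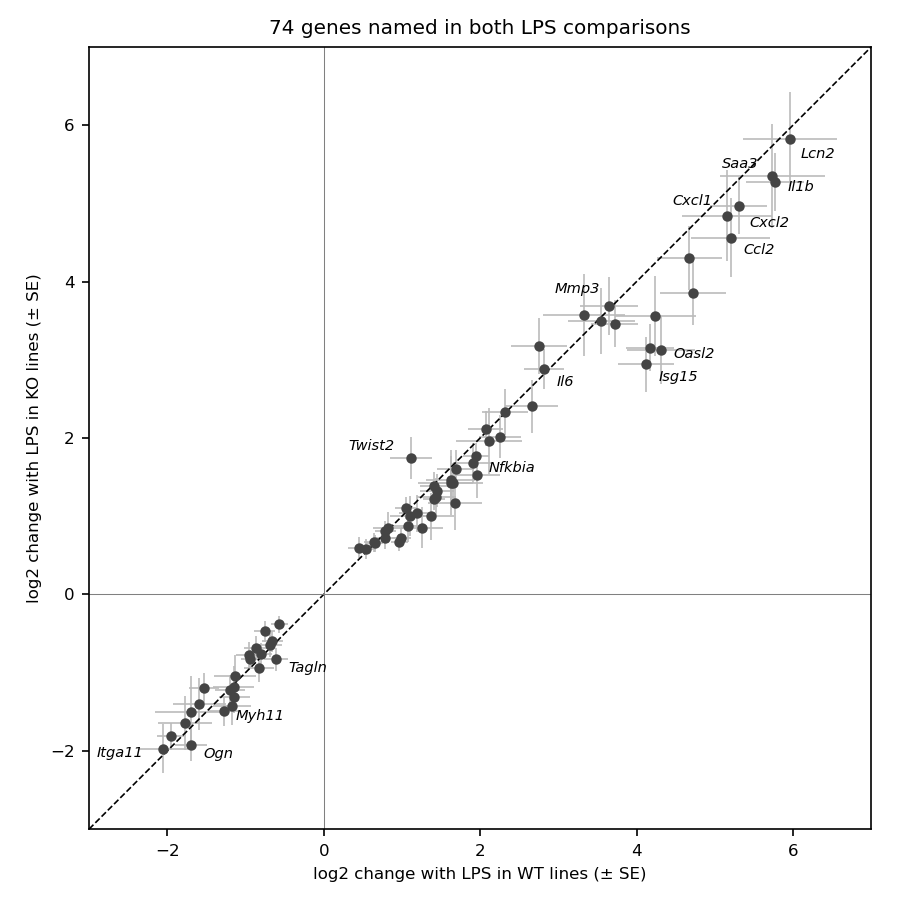
Log2 change with LPS in KO lines (vertical axis) against WT lines (horizontal axis) for the 74 genes named in both comparisons, with bars of 1 SE and a dashed line of equal change. All 74 points have the same sign on both axes, as did every gene called in both comparisons, and 52 have a larger absolute change in WT.

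Whether LPS acted differently in KO lines was tested as the difference between the 2 changes. Interferon-stimulated genes as a group had a smaller change in KO, 24 of 25 members with a negative difference and a median of -0.61 (camera adjusted p = 4.38e-08, adjusted p = 0.985 with an estimated correlation, fry adjusted p = 0.949), and the median ranged from -0.86 to -0.28 over 17 alternatives. Usp18 had a difference of -1.76 (SE 0.55) and Isg15 one of -1.18 (SE 0.50), and both had an adjusted p of 0.949 in limma. For both genes the genotypes lay farther apart without LPS than with it. Usp18 was at 8.38 to 10 in untreated KO against 6.92 to 8.31 in WT, and at 11.49 to 12.18 against 11.98 to 12.14 with LPS. Isg15 was at 8.62 to 10.01 against 7.8 to 8.94 untreated, and at 12.19 to 12.92 against 12.37 to 12.61 with LPS. The per-line median change of these genes was 1.98, 1.91 and 2.46 in WT5, WT7 and WT13, and 1.19, 2.04 and 1.73 in KO4, KO10 and KO15, so KO10 lay within the WT range. No single gene passed limma's test: 0 of 11060 genes were called, and 392 had an unadjusted p under 0.05. Camera passed no other of the 30 lists in this fit, and fry passed 0. With the line as a fixed block camera passed 3 lists, 1 higher and 2 lower, the interferon list among them. Chemokines had a median difference of -0.34 (adjusted p = 0.193), NF-kB feedback genes one of -0.09 (adjusted p = 0.631) and the IGF axis one of 0.12 (adjusted p = 0.165).

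The gene nearest to the threshold was Gm4951. It was detected on the 3 WT arrays with LPS and on 0 of the other 9, so its change in the KO lines was not measured above background and no size is given for the difference (adjusted p = 0.0601, limma). With the line as a random block the adjusted p was 0.0174, and with it as a fixed block 0.0609, with a range of 0.000108 to 0.934 over all alternatives. Gm4951 lies on chromosome 18. The next genes by p were Ajuba (0.63), Wnt7b (not detected in untreated WT lines), Aloxe3 (-0.79), Rprd2 (-0.82), Aven (-0.74), Miga1 (-0.81), Dcaf11 (-0.61), Metap2 (-0.77) and Iffo1 (0.59), each with an adjusted p of 0.949. Of these 10 genes with Gm4951, 5 had no probe detected on all 12 arrays. Aloxe3 in untreated WT (4.45 to 4.84) and Iffo1 in untreated KO (4.54 to 4.79) lay close to undetected Gm4951 (4.34 to 4.75), so their sizes are uncertain. Differences did not overlap between the genotypes for 12.3% of genes, where chance gives 10%.

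**Figure D4:**
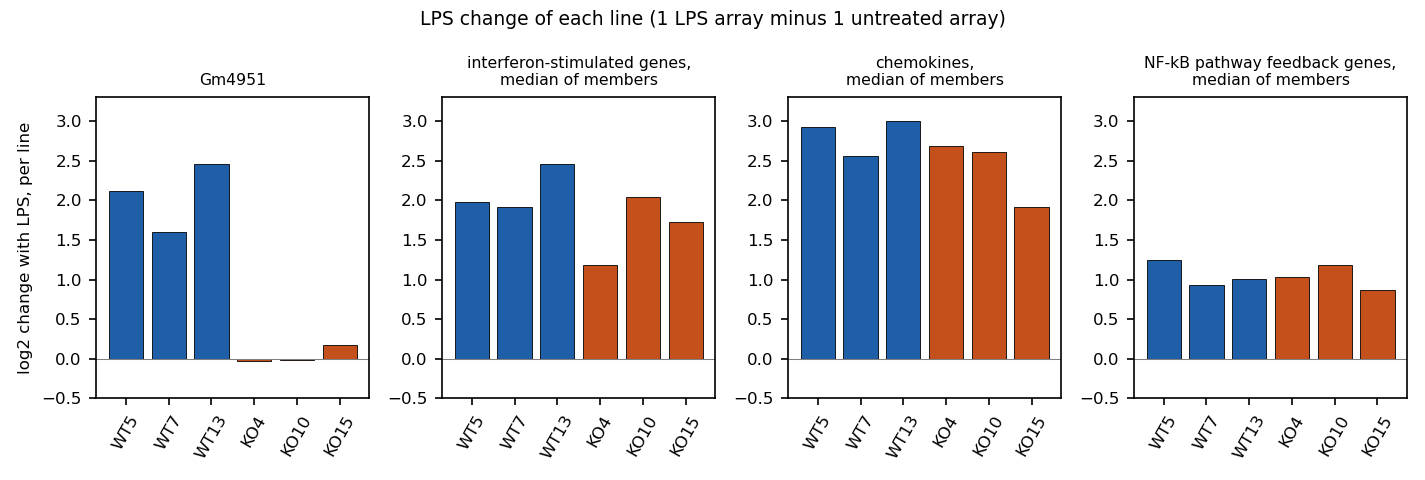
Log2 change with LPS in each of the 6 lines (1 LPS array minus 1 untreated array, no error bar) for Gm4951 and for the median of 3 gene lists. Gm4951 bars rest on untreated and KO arrays that did not detect it, while the NF-kB feedback genes changed by 0.93 to 1.25 in WT and 0.87 to 1.19 in KO.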

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

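All tests in this part other than the planned comparisons and the splits of the samples were chosen after the result was seen, including those for Gm4951.

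By camera with the preset correlation, interferon-stimulated genes had a smaller LPS change in KO (median difference -0.607, range -0.859 to -0.277 over 17 alternatives, adjusted p = 4.38e-08). The call was lost with an estimated correlation (adjusted p = 0.985) and in fry. The per-line median change of KO10 (2.04) lay within the range of the WT lines (1.91 to 2.46). Without LPS the list's median difference between genotypes was 0.328, and this higher untreated level in KO enters the smaller change. Gm4951, not on that list, was at least 3.41-fold lower in KO than in WT lines with LPS and was detected on the 3 WT arrays with LPS alone. Levels with LPS argue against a weaker interferon response of the KO lines as the whole cause of the lower Gm4951 level. The 22 interferon-stimulated genes called in WT differed between genotypes with LPS by a median of -0.17 (SD over genes 0.18, lowest -0.54), while Gm4951 was lower by at least 1.77. In LPS change, those 22 genes had a median of 71.9% of the WT change in KO (lowest 41.9%). The change of Gm4951 in KO was not measured above background, so the changes do not decide. Levels with LPS argue in the same way against fewer leukocytes overall in the KO lines, since the 18 leukocyte markers measured had a median of -0.323 (SD over markers 0.22, lowest -0.65). A sequence difference under the probe could hide the transcript in KO lines and stays open, as the gene's other probe was detected on 0 arrays. An effect of the genotype itself was not told apart from it.

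Signals also appeared in probes outside the named genes. Of 3238 kept probes without a single gene name, 3 (0.0926%) differed between genotypes without LPS and 2 (0.0618%) with LPS, against 0.14% and 0.257% of the named probes. With LPS, 593 (18.3%) of them changed in WT and 351 (10.8%) in KO, against 21.1% and 12.8% of the named probes.

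Other groupings of the arrays were tried with the 10 splits of 6 samples into 3 and 3, too few for a share under 0.05. The real split called 20 genes without LPS against at most 0 for the others, 36 with LPS against at most 1, and 14 on line means against at most 0. For LPS in WT and in KO it called 2526 and 1622 against at most 0. In those comparisons 4 of the 10 splits, the real one included, part all 3 pairs, and the highest other of these was 0. In each of these 5 comparisons 1 split, the real one, reached its count. Each other split mixes the real groups, so a real difference widens its spread, and its count is no estimate of false calls. For the difference in LPS change the real value of 0 was reached by 10 of 10 splits.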

How the results depend on the processing

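The settings with sex as a term, the leukocyte covariate and the lines WT13 or KO4 left out were chosen after seeing the data. No named gene changed direction while called, under any of the alternatives run. Of the values of named genes under alternatives, 380 of 521 kept their side of the threshold without LPS, 455 of 645 with LPS, 253 of 359 on line means, 2338 of 2482 for LPS in WT, 2156 of 2310 for LPS in KO and 289 of 293 for the difference. Named genes called under every alternative that gave a value numbered 3 of 19, 3 of 24, 2 of 14, 71 of 104 and 65 of 97 in the first 5 comparisons. Counts within 1.5 times the main one came from 12 of 24, 13 of 24, 2 of 19, 20 of 24, 17 of 24 and 26 of 30 alternatives. No background correction and the authors' processed values are near the same setting and not independent alternatives. Both called 15 genes without LPS, 33 with LPS and 3 on line means, and 2792 and 2795 for LPS in WT.

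The cause was not tested for the values that follow, except where fewer arrays, more or fewer probes tested, or an added covariate is the change itself. Without LPS (20 genes) the count was 32 with normexp and an offset of 50, 37 with a variance trend, 194 with array weights, 3 with only the arrays compared, 11 without line WT13 and 41 with the leukocyte covariate. With LPS (36) it was 17 with no filter on dim probes, 101 with array weights, 7 with only the arrays compared, 14 on line means, 19 without line WT13 and 64 with the leukocyte covariate. On line means (14) it was 3 with no background correction, 3 with the authors' processed values, 29 with normexp and an offset of 50, 27 with scaling to the 75th percentile, 5 with no filter, 24 with detection on all 12 arrays, 8 with the mean over probes, 40 with a variance trend, 47 with array weights, 9 with sex as a term and 44 with the leukocyte covariate. For LPS in WT (2526) it was 4375 with all probes and 1097 without line WT13. For LPS in KO (1622) it was 2634 with all probes, 2476 with array weights and 925 without line KO4. For the difference (0) it was 1 gene, Gm4951, with a variance trend (adjusted p = 0.0205) and with array weights (adjusted p = 0.00262).

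With 1 array left out, the counts ran from 5 to 46 without LPS, 6 to 27 with LPS, 3 to 49 on line means (1 line left out), 1581 to 3020 for LPS in WT, 808 to 1441 for LPS in KO and 0 to 1 for the difference, where the 1 gene came without the WT7 LPS array. The arrays that moved a count of genes by over 1.5 times are given with their counts in the report. The lists called ran from 6 to 12 without LPS (9), 5 to 11 with LPS (8, and 5 without either WT5 or KO15), 7 to 16 on line means (10, and 16 without KO4), 11 to 11 for LPS in WT (11), 11 to 12 for LPS in KO (11) and 1 to 7 for the difference (1). That last count was 5 without the untreated KO4 array, 7 without the KO10 LPS array and 2 without the LPS array of WT13, KO4 or KO15. The leukocyte list on line means changed sign without KO4 (adjusted p = 0.705, median 0.014), within a range of 2.87e-13 to 0.705.

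The paired fits used the line as a block. With the fixed block LPS called 2992 genes in WT and 1922 in KO and the difference 0, and with the random block 28 without LPS, 43 with LPS, 3274 for LPS in WT, 2136 for LPS in KO and 1 for the difference. With the fixed replicate block the difference had 3 lists called in place of 1. The pairing changed no other call of a count by over 1.5 times. With an estimated correlation camera called 0 of 30 lists in each of the 6 comparisons, and fry called 1, 5, 3, 16, 12 and 0. With the leukocyte covariate 2 lists were called for the difference.

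Signal over background limits dim genes: 11060 genes were tested after the filter, and bounds replace folds where a group was not detected. No bounds were computed for line means or for the difference of LPS changes. No scaling moved the median of all genes by over 0.1.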

Other observations

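All tests and gene families in this part were chosen after the values were seen.

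Members of other gene families changed with LPS, and the families as such were not tested. Over all genes, 22.8% were called in WT and 14.7% in KO. Of 6 prolactin family genes, 4 rose in WT and 4 in KO, with medians of 1.89 and 1.49, and these included the proliferin genes Prl2c2 (2.00, SE 0.34, adjusted p = 0.00184 in WT, and 1.90, SE 0.34, adjusted p = 0.00345 in KO) and Prl2c3 (1.80 and 1.65). All 3 guanylate-binding protein genes measured rose in both genotypes (medians 2.35 and 2.10), and of 10 proteasome beta subunit genes 6 rose in WT and 3 in KO (medians 0.31 and 0.16). C1q and TNF related genes fell in 4 of 7 cases in each genotype (medians -0.35 and -0.47). Of 7 chaperonin subunit genes 4 rose in WT and 1 in KO (medians 0.42 and 0.21), and the difference between genotypes was called for 0 of these 7. Of 56 ribosomal protein genes 4 rose and 1 fell in WT, and 1 rose in KO.

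Both Tmem176 genes measured rose with LPS in both genotypes (medians 2.21 in WT and 1.88 in KO), and Tmem176a stood beside the called Tmem176b between genotypes without LPS at 1.52 (SE 0.32, adjusted p = 0.0939). Of the iroquois homeobox genes, Irx1 (1.20, SE 0.30, adjusted p = 0.167) and Irx2 (1.70, SE 0.46, adjusted p = 0.204) were positive in KO without LPS and Irx3 was at -0.40 (SE 0.12, adjusted p = 0.27), and none of the 3 passed.

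Genes that differed between genotypes were concentrated on chromosome 18, which carries miR-143/miR-145. Of 44 genes called in any genotype comparison 8 lay there (Stard4, Gm4951, Ccbe1, Pmaip1, Spire1, Stard6, Poli and Neto1), 2.82% of the 284 tested genes of that chromosome against at most 0.85% elsewhere, which argues against an even spread over the chromosomes (odds ratio 8.63, Fisher's exact test, two-sided, p = 1.37e-05). In the gene order of GRCm38.p6 they lay on average 45.5 tested genes from the microRNA locus, against 86.6 for the other tested genes of the chromosome (one-sided permutation test, 100000 permutations, p = 0.0203), although neighbours such as Stard6 and Poli are not independent. The nearest called gene, Gm4951, lay 16 tested genes from the locus and the farthest, Stard4, lay 128. No gene on the list of neighbours of the locus was called. A stretch of chromosome from the strain in which the null allele was made could give this concentration. These arrays cannot separate that hypothesis from an effect of the microRNAs on these genes. A sequence difference under 1 probe is argued against for 2 of the genes (Pmaip1 and Ccbe1), which have another probe called in the same direction, and stays open for the other 6. One of these, Spire1, has 3 other detected probes, of which 0 were called in the same direction and 2 had the opposite sign.

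Chemokine mRNA after LPS followed the leukocyte marker level of the line. Over the 6 lines the chemokine median and the leukocyte marker median of the LPS arrays correlated at r = 0.927 (exact permutation p = 0.00139, adjusted over 29 lists 0.0403) and Spearman's coefficient was 1 (exact p = 0.00278, adjusted 0.0806), and at r = 0.989 without KO4 and KO10. Leukocytes in the cultures might add chemokine mRNA: with the marker level of the untreated arrays r was 0.846 (exact permutation p = 0.0403, adjusted 0.403) and Spearman's coefficient 0.771 (exact p = 0.103), and r fell to 0.422 without WT5 and KO10, so that relation rests on those lines and the question stays open. A stronger LPS response of the whole line was not told apart from this, since NF-kB feedback genes gave r = 0.324 (exact permutation p = 0.525). Chemokines were not alone in following the marker median of the LPS arrays. Endoplasmic reticulum stress genes gave r = 0.918 (exact permutation p = 0.0375, adjusted 0.362) and interferon-stimulated genes r = 0.839 (exact permutation p = 0.0153, adjusted 0.222). The remaining lists lay between -0.658 (cell cycle) and 0.738 (Hox). Some leukocyte markers themselves changed with LPS, such as Adgre1 and C1qc.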
